A study of Mus musculus with 37 samples.

How the data were processed

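Messenger and other RNA was measured in lung tissue of 37 C57BL/6 mice, each giving 1 library. Per the labels' protocols, total RNA was extracted with Trizol, cDNA was made with the SMART-seq v4 kit, and libraries were prepared with Nextera XT, which does not mark strand. Per the submitters' processing notes, FastQC 0.11.4, MultiQC 1.12, Trimmomatic 0.36, STAR 2.5.2 and HTSeq 0.13.5 were used with the mouse build mm10, without a stated role for each. Their settings, the gene annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and members of gene families with near-identical copies, such as ribosomal protein genes and their pseudogenes, are uncertain. The deposited table holds whole-number read counts per gene symbol, not normalized by the authors, for 24421 symbols. Of these, 23336 (95.56%) matched a symbol of GENCODE M21 on mm10 (GRCm38), from which all coordinates were taken.

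Groups and sex were taken from the labels: mock, mock + NR, silicon, silicon + NR, GCR and gamma. Replicate numbers were given in accession order and only name a mouse. No library was left out of the main comparisons. Every pair of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom from 19.18 to 1003), so none was counted as a copy of another. Amplification of cDNA without molecular identifiers means that counts are not independent molecules. Counts per 1000000 (CPM) were computed here from the deposited counts and the library totals.

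Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, by the quasi-likelihood test with TMM normalization, after filterByExpr left 16977 genes. The model held the 6 groups and sex over all libraries, so that all comparisons share 1 estimate of the spread, and a model of 12 group-by-sex means was used for radiation within each sex and for its interaction with sex. Every p was adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Log2 fold changes carry the standard error obtained from the fold change and its F value. The median biological coefficient of variation was 0.41, with 3.09 prior degrees of freedom.

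Gene lists were fixed before the data were examined, 57 of pathways and of cell types of lung and of tissues that a dissection can include. Of these, 56 had measured members, and 58 of their 1173 distinct genes stood in more than 1 list. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction. With an estimated correlation only the p53 targets in silicon + NR against mock + NR and the sex label genes in females against males were called. A count adjusted over the list alone uses the p values of that list's members only.

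Genes named in the text follow a rule set before the data were examined. It took the 8 genes that rose most and the 8 that fell most among called genes with a mean log2 CPM of at least 2, leaving out predicted genes and sex label genes, and the 3 members of smallest p of each called list. Where fewer than 5 genes passed it took the 4 of smallest p in each direction, as values that did not pass. It also took 5 fixed p53 targets (Cdkn1a, Mdm2, Phlda3, Eda2r and Bax) and 5 fixed NAD genes (Nmrk1, Nampt, Nnmt, Cd38 and Sirt1). The rule gives more genes than the text can hold, so examples were taken from it. Of the 5 genes called in gamma against mock, 3 outside the rule (Lingo1, Ddx3y and Eif2s3y) were named after their values were seen.

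Correlations of fold changes between radiation types share the mock mice, so unchanged groups were simulated 100 times against those controls, and the mock mice were also split in 70 ways into separate parts for each comparison. The alternatives planned before the data were examined were DESeq2 1.42.0, RLE size factors, no count filter, limma voom with sample quality weights, no sex term, a fit of only the groups compared, and leaving out each library in turn. Chosen after the data were seen were fits without the 13 libraries over 1000 CPM of Acta1, without the 4 over 100000 CPM of Rn45s, without either kind (21 libraries left), and with the mean of the skeletal muscle list and the level of Rn45s as covariates. Without the muscle-rich libraries 24 were left, 2 of them silicon. Also chosen after the data were seen were fits without the 3 lymphoid-rich libraries over 100 CPM of Ccl19 (34 left) and without the 2 heart-rich libraries over 10000 CPM of Nppa (35 left). Gene lists were tested again without each of these 4 kinds of library. Up to 40 splits of the samples, the real one included, were refitted for each comparison.

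The gene test was checked on simulated counts drawn from the real means and library sizes, with 200 changed genes. In silicon against mock it recovered 63% of 2-fold and 95% of 4-fold changes, in GCR against mock 65% and 93%, in gamma against mock 56% and 87%, in silicon + NR against mock + NR 40% and 87%, in mock + NR against mock 57% and 86%, and in silicon + NR against silicon 59% and 92%. In the list test for GCR against mock, 5 of 5 shifted lists and 0 of 45 others were called. The simulation was not given the tissue differences of real libraries or the correlation of real lists. It thus tests neither the preset correlation nor recovery in the real libraries.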

Results

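Lung RNA was measured by sequencing in 37 C57BL/6 mice, with 1 library per mouse, after 0.75 Gy of 1 of 3 kinds of radiation or after a mock exposure at 0 Gy. The kinds were accelerated silicon ions, a simplified mixture of 5 ions that simulates galactic cosmic radiation (GCR), and gamma rays from a caesium source. Some mice drank water with 12 mM nicotinamide riboside (NR), a vitamin B3 form from which cells make NAD, from before the exposure onwards. The groups were mock (7 mice), mock + NR (5), silicon (7), silicon + NR (6), GCR (7) and gamma (5). By their labels 22 mice were male and 15 female, with 5 males and 2 females in mock, 3 and 4 in silicon, 3 and 4 in GCR, and 3 and 2 in gamma. Of the NR groups, mock + NR had 4 males and 1 female, and silicon + NR 4 and 2. Total counts ran from 9485197 (GCR replicate 6) to 66381526 (GCR replicate 4), with a median of 28476462. The time between exposure and dissection is not given in the sources used here. The animal numbers of the GCR mice are written in another style in the labels than those of the other groups, and whether these mice formed a separate cohort or batch is not given in the sources used here.

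The libraries differed in what tissue they held. Acta1, the actin of skeletal muscle (mm10, chromosome 8, 123891769 to 123894751), exceeded 1000 counts per 1000000 (CPM) in 13 libraries, namely 4 of 7 mock, 2 of 5 mock + NR, 5 of 7 silicon and 2 of 6 silicon + NR. It did so in 0 of the 12 GCR and gamma libraries. This difference between GCR with gamma and the other groups had p = 0.0023 by Fisher's exact test (both sides), chosen after the values were seen. Its mean was 8250 ± 10200 CPM in mock (SD, n = 7), 14500 ± 13200 in silicon (n = 7), 20.4 ± 13.8 in GCR (n = 7) and 9.73 ± 4.94 in gamma (n = 5). Krt5, a keratin of basal squamous cells (chromosome 15, 101707070 to 101712898), averaged 169 ± 174 CPM in mock and 2.39 ± 4.53 in GCR. Rn45s, the precursor of the ribosomal RNAs, exceeded 100000 CPM in 4 libraries, GCR replicates 2, 5 and 6 and mock replicate 4. Those 4 libraries also had the 4 smallest totals. Ccl19, a chemokine of lymphoid stroma, was at 447 and 232 CPM in silicon replicates 3 and 6 and at 419 in mock + NR replicate 4, and at most at 21.4 elsewhere. Nppa, the atrial natriuretic peptide gene, was at 17519 and 24514 CPM in gamma replicates 3 and 4 and at most at 2740 elsewhere. Fits without these 3 lymphoid-rich or these 2 heart-rich libraries were chosen after the data were seen. Scgb1a1, the main secretory protein of club cells in the airways, took 2.5% to 30.1% of all counts in a library.

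**Figure D1:**
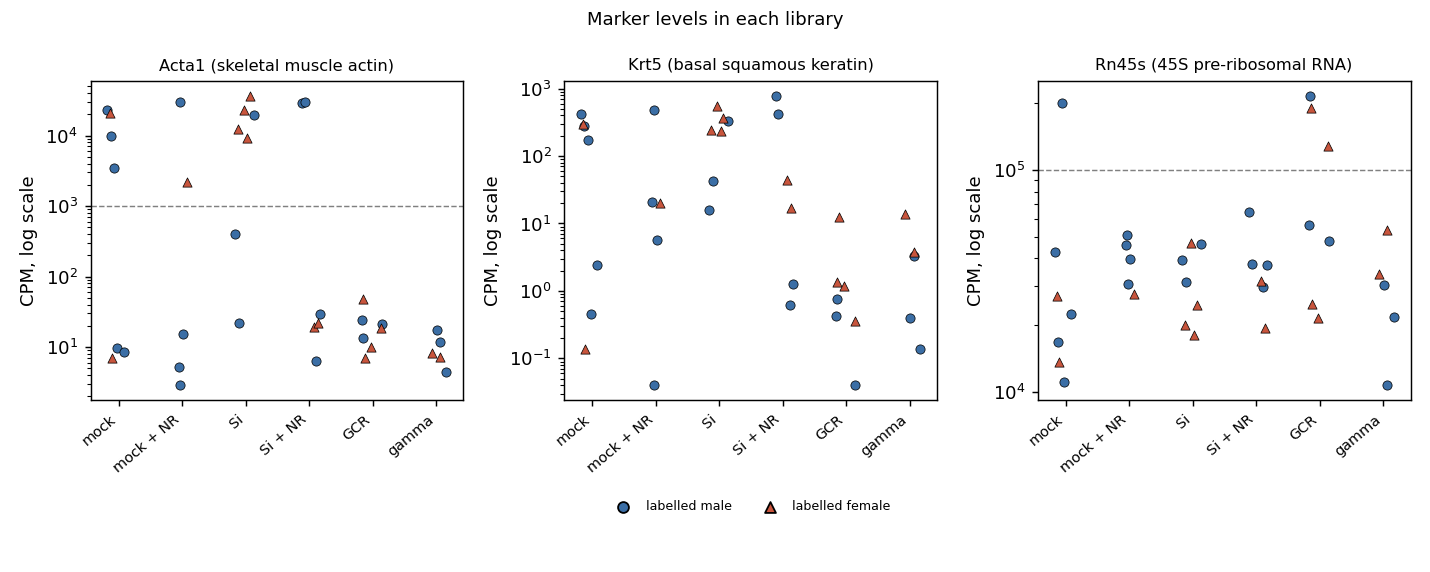
CPM (log scale) of Acta1, Krt5 and Rn45s in each of the 37 libraries by group, with circles for mice labelled male and triangles for mice labelled female. Dashed lines mark 1000 CPM of Acta1, exceeded in 13 libraries, and 100000 CPM of Rn45s, exceeded in 4.

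The sex labels were checked with Xist, the RNA that silences an X chromosome in females (chromosome X, 103460366 to 103483254), and with genes of the Y chromosome. These genes went with the label in every library but 1. The library labelled female gamma replicate 5 had 3.73 CPM of Xist and 87.6 CPM of the Y-linked Ddx3y, against its label. It was kept under its label in every comparison. Across all mice 5 genes were higher and 5 lower in females (edgeR's quasi-likelihood test). Xist differed by 6.05 on the log2 scale (SE 0.32), and the X-linked Kdm6a, Kdm5c and Eif2s3x, which escape X inactivation, by 0.68, 0.52 and 0.49 (SE 0.12, 0.08 and 0.08). The Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d stood at -8.56, -8.49, -7.83 and -7.72 (SE 0.94, 0.94, 0.87 and 0.90). Among 56 gene lists the sex label genes had camera adjusted p = 1.49e-24, and adjusted p = 5.3e-07 with an estimated correlation. Ribosomal protein genes were lower in females in all 30 members, with none passing singly (median -0.22, camera adjusted p = 5.88e-14, and adjusted p = 0.75 with an estimated correlation). Without the muscle-rich libraries, a limit set after the data were seen, 2 of the 10 genes were called. The ribosomal protein median was then -0.08 (camera adjusted p = 0.0358, and adjusted p = 0.91 with an estimated correlation).

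The silicon comparison asks what the ions did to the lung without NR. Endothelial genes were lower in silicon than in mock lungs and cell division genes were higher, but 0 single genes passed. All 24 measured endothelial genes were lower (median log2 fold change -1.25, camera adjusted p = 1.52e-22, and adjusted p = 0.34 with an estimated correlation), and 22 passed when adjusted over the list alone. Tmem100, a target of BMP signalling in vessels (chromosome 11, 90030348 to 90036508), stood at -2.01 (SE 0.44), Ramp2, a co-receptor for adrenomedullin, at -2.10 (SE 0.48), and Sox18, a vascular transcription factor, at -1.24 (SE 0.30). Of the 17 alveolar type 1 genes, which mark the flat gas exchange cells, all were lower (median -0.77, camera adjusted p = 3.15e-10, and adjusted p = 0.4 with an estimated correlation), with 2 passing when adjusted over the list alone. All 32 cell cycle genes were higher, 22 of them when adjusted over the list alone (median 0.98, camera adjusted p = 4.33e-14, and adjusted p = 0.4 with an estimated correlation). The mitotic checkpoint gene Bub1b and the kinase gene Cdk1 stood at 0.96 (SE 0.32) and 0.99 (SE 0.35). B cell genes were higher in 19 of 19 members (median 2.06, camera adjusted p = 5.87e-07, and adjusted p = 0.57 with an estimated correlation), and T cell genes in 23 of 23 (median 1.94, camera adjusted p = 0.000199, and adjusted p = 0.73 with an estimated correlation). Adjusted over the list alone, 17 B cell and 19 T cell genes passed, among them Ccr7, the homing receptor of lymphocytes, at 3.18 (SE 0.92). The p53 targets were not called (median 0.10), and Cdkn1a, the cell cycle inhibitor p21, stood at 0.32 (SE 0.37). Beside these groups, Acta1 exceeded 1000 CPM in 5 of the 7 silicon and 4 of the 7 mock libraries, and mock replicate 4 was high in Rn45s. Silicon replicates 3 and 6 were the lymphoid-rich ones, with T cell means of 5.85 and 5.04 log2 CPM. The B cell median without the lymphoid-rich libraries was 0.45 and the list was not called (camera adjusted p = 0.0963). The T cell median was then -0.32 (camera adjusted p = 0.0107, and adjusted p = 0.71 with an estimated correlation), and Ccr7 stood at -0.05 (SE 0.47). The cell cycle median was 0.68 (camera adjusted p = 9.4e-06, and adjusted p = 0.71 with an estimated correlation) and the endothelial one -1.14 (camera adjusted p = 4.53e-16, and adjusted p = 0.6 with an estimated correlation).

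By edgeR 0 of 16977 genes passed for silicon against mock (smallest adjusted p = 0.0897), with 2185 at an unadjusted p under 0.05, while DESeq2 called 425 and voom with quality weights 1. Leaving out mock replicate 3 or 6 gave 163 or 307 genes, and leaving out the muscle-rich libraries, chosen after the data were seen, gave 725, with 3 mock mice and silicon replicates 1 and 3 left, of which replicate 3 is lymphoid-rich. In that fit 21 endothelial genes fell (median -2.41, camera adjusted p = 4e-27, and adjusted p = 0.26 with an estimated correlation). So did 12 alveolar type 1 genes (median -2.29, camera adjusted p = 8.22e-16, and adjusted p = 0.31 with an estimated correlation). Without the lymphoid-rich libraries edgeR called 0, with 1337 at an unadjusted p under 0.05.

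GCR lungs differed from mock lungs in 2811 genes, 1364 higher and 1447 lower, and the largest falls were in muscle and keratin genes. Skeletal muscle genes fell in 18 of 21 measured members (median -7.33, camera adjusted p = 0.000514, and adjusted p = 0.96 with an estimated correlation), among them Acta1 at -8.43 (SE 2.29), the fast troponin gene Tnnt3 at -7.33 (SE 1.84) and the myosin gene Myh4 at -8.88 (SE 2.41). Squamous epithelium genes fell in 13 of 18 (median -5.83, camera adjusted p = 0.000614, and adjusted p = 0.96 with an estimated correlation), with Krt4 at -7.05 (SE 1.88), Krt13 at -7.02 (SE 1.93) and Krt5 at -6.79 (SE 1.86). Adjusted over the list alone, 20 muscle and 16 squamous genes passed. In these lists Acta1 exceeded 1000 CPM in 4 of 7 mock and in 0 of 7 GCR libraries. Without the muscle-rich libraries the muscle list was called in the other direction (median 0.60, camera adjusted p = 0.00974, and adjusted p = 0.99 with an estimated correlation), and the squamous list was not called (median -0.13, camera adjusted p = 0.556). Ribosomal protein genes rose in 17 of 30 members, 23 when adjusted over the list alone (median 0.69, camera adjusted p = 1.72e-09, and adjusted p = 0.96 with an estimated correlation), with Rplp1 at 1.84 (SE 0.36) and Rps14 at 1.26 (SE 0.28). The snoRNA gene Snora81 rose by 5.03 (SE 0.88) and the RNase P RNA gene Rpph1 by 4.23 (SE 0.77). Rn45s was over 100000 CPM in 3 of the 7 GCR libraries and in 1 of the 7 mock libraries. Without these 4 libraries Snora81 stood at 2.49 (SE 0.75) and Rpph1 at 2.66 (SE 0.59), neither called. The ribosomal protein median was then 0.44 (camera adjusted p = 4.78e-07, and adjusted p = 0.97 with an estimated correlation). Of the GCR libraries left, replicate 1 had a ribosomal protein mean of 9.05 log2 CPM, and the fewest genes with counts of all libraries (16168). Replicates 3, 4 and 7 had means of 7.83, 7.45 and 7.74, within the range of all mock libraries (7.43 to 8.44).

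Immediate early genes, transcribed within minutes of a stimulus, rose in 11 of 24 members in GCR lungs and none fell, and adjusted over the list alone 15 rose and 1 fell (median 0.86, camera adjusted p = 2.12e-07, and adjusted p = 0.96 with an estimated correlation). Egr1, a zinc finger transcription factor (chromosome 18, 34859823 to 34864984), rose by 2.10 (SE 0.38), its relative Egr3 by 2.53 (SE 0.52) and the AP-1 gene Fosl2 by 1.03 (SE 0.20). Areg, an epithelial growth factor, rose by 2.15 (SE 0.41). Ciliated cell genes rose in 7 of 26 members, 9 when adjusted over the list alone (median 0.69, camera adjusted p = 4.03e-05, and adjusted p = 0.96 with an estimated correlation), with the dynein gene Dynlrb2 at 1.35 (SE 0.36) and Cfap126 at 1.21 (SE 0.35). The ciliated median without the high-Rn45s libraries was 0.39 (camera adjusted p = 0.00124, and adjusted p = 0.97 with an estimated correlation). Of the p53 targets, Mdm2, which restrains p53, rose by 0.37 (SE 0.12), Phlda3 fell by 1.44 (SE 0.39), and Cdkn1a at -0.32 (SE 0.37) did not pass. Over that list 5 genes rose and 4 fell of 30, and camera did not call it.

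The GCR count did not hold without either kind of unusual library. It was 0 without the muscle-rich libraries, 0 without the 4 high-Rn45s libraries and 0 with muscle and Rn45s levels as covariates, limits chosen after the data were seen, and 909 in a fit of only GCR and mock. Leaving out single libraries gave 501 to 4087 genes, as listed further below.

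Gamma lungs had higher Egr1 than mock lungs, at 146 ± 88.5 CPM (SD, n = 5) against 23.1 ± 7.57 (n = 7). Egr1 rose by 2.70 on the log2 scale (SE 0.41, adjusted p = 0.00281 by edgeR), and the transmembrane protein gene Tmem108 by 2.48 (SE 0.44, adjusted p = 0.0211). The other 3 genes called were Lingo1 (2.48, adjusted p = 0.0427) and the Y-linked Ddx3y (6.63, adjusted p = 0.0388) and Eif2s3y (6.41, adjusted p = 0.0417). These 3 fall outside the rule for named genes and were named after their values were seen, and without the library labelled female gamma replicate 5 the Y-linked pair stood at 0.28 and -0.10. Immediate early genes were higher in 19 of 24 members, with 1 rising and 10 when adjusted over the list alone (median 0.48, camera adjusted p = 7.37e-11, and adjusted p = 0.32 with an estimated correlation), with Fos at 2.28 (SE 0.57) and Fosb at 2.88 (SE 0.68), which did not pass. Cell cycle genes were lower in 31 of 32 members, none passing (median -0.85, camera adjusted p = 2.76e-09, and adjusted p = 0.65 with an estimated correlation). Heat shock genes were lower in 15 of 15, with 6 passing when adjusted over the list alone (camera adjusted p = 2.76e-09, and adjusted p = 0.33 with an estimated correlation), as Hspa8, a constitutive chaperone, at -1.12 (SE 0.33). Mesothelial genes were higher in 12 of 13, with 5 when adjusted over the list alone (camera adjusted p = 3.78e-06, and adjusted p = 0.32 with an estimated correlation), as Lrrn4 at 2.58 (SE 0.67). Skeletal muscle genes were lower in 20 of 21, with 15 when adjusted over the list alone (median -6.78, camera adjusted p = 2.76e-09, and adjusted p = 0.65 with an estimated correlation), in a group with 0 of 5 muscle-rich libraries against 4 of 7 in mock. The skeletal muscle median without the muscle-rich libraries was 0.81, in the other direction (camera adjusted p = 0.00135, and adjusted p = 0.52 with an estimated correlation). The cell cycle median was then -0.50 (camera adjusted p = 4.23e-06, and adjusted p = 0.52 with an estimated correlation) and the immediate early median 0.28 (camera adjusted p = 0.00058, and adjusted p = 0.53 with an estimated correlation). Cell cycle means stood apart in mock replicate 6, a muscle-rich library, at 3.57 log2 CPM (2.08 to 2.60 in the other mock libraries). They also did in gamma replicate 4, at 1.42 (1.95 to 2.14 in the other gamma libraries). Cdkn1a stood at -0.69 (SE 0.41). The highest Egr1, 220 and 261 CPM, was in the heart-rich gamma replicates 3 and 4, against 59.3 to 104 in the other 3. Without those 2 libraries Egr1 stood at 1.87 (SE 0.41, adjusted p = 0.18 by edgeR), Tmem108 at 1.20 (SE 0.41, adjusted p = 0.42) and Lingo1 at 1.83 (SE 0.53, adjusted p = 0.42), while both Y-linked genes were still called. The heat shock median was then -0.89 (camera adjusted p = 3.95e-09, and adjusted p = 0.58 with an estimated correlation), against -0.57 with all libraries.

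EdgeR called 0 genes for gamma without the muscle-rich libraries (chosen after the data were seen) and 0 in a fit of only gamma and mock. DESeq2 called 259, with all 5 among them, and voom with quality weights 238, with 3 of the 5. In the 2 edgeR fits Egr1 stood at 2.48 and 2.63, Tmem108 at 2.42 and 2.49, and Lingo1 at 2.23 and 2.53, and the Y-linked Ddx3y at 5.17 and 2.12 and Eif2s3y at 5.01 and 1.84. Without the lymphoid-rich libraries 2 genes were called, and without the heart-rich ones 4, of which 2 were among the 5. Leaving out 1 library gave 1 to 18 genes, as listed further below.

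**Figure D2:**
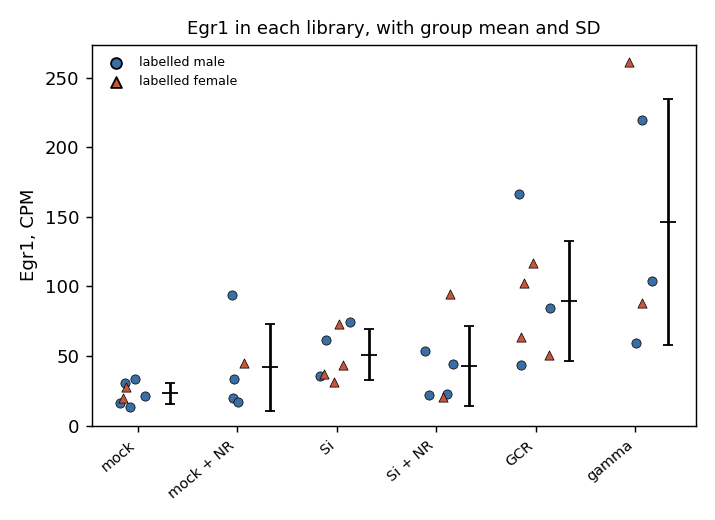
Egr1 in each library in CPM (linear axis from 0), by group, with circles for mice labelled male, triangles for mice labelled female, and the group mean with SD beside the points. Mock libraries lie between 13.3 and 33.6 CPM and gamma libraries between 59.3 and 261.

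Taking silicon, GCR and gamma as 1 average against mock, Egr1 rose by 1.99 (SE 0.34, adjusted p = 0.0305 by edgeR) and Zbtb16, a transcription factor induced by glucocorticoids (chromosome 9, 48654297 to 48836222), fell by 1.45 (SE 0.27, adjusted p = 0.0468). Immediate early genes were higher in 21 of 24 members, 12 when adjusted over the list alone (median 0.49, camera adjusted p = 2.25e-12, and adjusted p = 0.32 with an estimated correlation). Egr3 at 2.04 (SE 0.46) and Fosb at 2.46 (SE 0.58) did not pass. Endothelial genes were lower in 23 of 24, with 3 when adjusted over the list alone (median -0.61, camera adjusted p = 2.28e-07, and adjusted p = 0.96 with an estimated correlation), Tmem100 standing at -1.30 (SE 0.33). Glucocorticoid response genes were lower in 12 of 18, 1 of which fell and 4 when adjusted over the list alone (camera adjusted p = 0.00377, and adjusted p = 0.96 with an estimated correlation), with Map3k6 at -1.25 (SE 0.25). Zbtb16 averaged 73.4 ± 32.2 CPM in mock (SD, n = 7) and between 24.4 and 34.3 in the other 5 groups, including 27 ± 14.1 in mock + NR (n = 5). Mean Egr1 was 23.1 CPM in mock, 41.8 ± 31.2 in mock + NR, 50.8 in silicon, 89.7 in GCR and 146 in gamma. The endothelial median without the muscle-rich libraries was -1.23 with 11 genes falling (camera adjusted p = 1.39e-22, and adjusted p = 0.28 with an estimated correlation). The immediate early median was then 0.29 (camera adjusted p = 0.00194, and adjusted p = 0.68 with an estimated correlation). Glucocorticoid response genes had a median of -0.25 without the high-Rn45s libraries (camera adjusted p = 0.00763, and adjusted p = 0.99 with an estimated correlation), against -0.38 with all. Acta1 exceeded 1000 CPM in 5 of the 19 irradiated mice without NR and in 4 of 7 mock mice. The 2 calls became 0 without the high-Rn45s libraries and 170 without the muscle-rich ones (both chosen after the data were seen), 1 with RLE size factors, where Zbtb16 was lost, and 176 by DESeq2. Without the lymphoid-rich libraries edgeR called 0 (2067 at an unadjusted p under 0.05), with Egr1 at 2.01 (SE 0.36) and Zbtb16 at -1.36 (SE 0.26). Without the heart-rich libraries Egr1 stood at 1.73 (SE 0.32, adjusted p = 0.0473). Leaving out 1 library gave 0 to 30 genes, and 0 or 1 without most, as listed further below.

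Fold changes of the 3 radiation types against the same mock mice were compared across 16977 genes, which are not independent replicates. Silicon and GCR had Pearson r = -0.26 (covariance -0.0929), where simulated unchanged groups with a shared, redrawn mock group gave a median of 0.55 (central 95% from -0.07 to 0.88). Their simulated covariance had a median of 0.0862 (-0.00598 to 0.252), so that both observed values lay below the range. Silicon and gamma had r = -0.14 (covariance -0.0346), against a simulated 0.43 (-0.32 to 0.83) and a covariance of 0.0580 (-0.0486 to 0.241), both observed values lying inside. GCR and gamma had r = 0.62 (covariance 0.278), against a simulated 0.52 (-0.02 to 0.79) and a covariance of 0.0718 (-0.00117 to 0.241). Their r lay inside the range that unchanged groups give and their covariance above it. With the mock mice split into separate parts for each comparison the medians over 70 splits were -0.32, -0.24 and 0.43. Without the muscle-rich libraries, chosen after the data were seen, the 3 values were 0.28, 0.47 and 0.42. Spearman's rho with all libraries was -0.12, 0.1 (opposite in sign to r) and 0.44. GCR and gamma shared 1 higher gene, Egr1, where independent lists would share 0.4.

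NR in unirradiated mice was tested by comparing mock + NR with mock. Endothelial genes were lower in 24 of 24 members, 23 when adjusted over the list alone (median -1.32, camera adjusted p = 8.11e-19, and adjusted p = 0.39 with an estimated correlation), with Tmem100 at -2.07 (SE 0.48) and Tek, the angiopoietin receptor, at -1.57 (SE 0.40). Alveolar type 1 genes were lower in 16 of 17, with 12 when adjusted over the list alone (median -0.87, camera adjusted p = 6.44e-08, and adjusted p = 0.5 with an estimated correlation), as Emp2 at -1.18 (SE 0.36). Ciliated cell genes were higher in 26 of 26, with 24 when adjusted over the list alone (median 0.99, camera adjusted p = 7.27e-14, and adjusted p = 0.4 with an estimated correlation), as Sntn at 1.23 (SE 0.36) and Tmem212 at 1.28 (SE 0.39). Club cell genes were higher in 17 of 18, none passing (median 0.77, camera adjusted p = 0.000479, and adjusted p = 0.57 with an estimated correlation), as Scgb1a1 at 1.11 (SE 0.52). NAD metabolism genes were not called (median 0.05 over 36 genes), and Nmrk1, the kinase that phosphorylates NR, stood at 0.14 (SE 0.16), Nampt at -0.22 (SE 0.24), Nnmt at -0.98 (SE 0.47), Cd38 at -0.26 (SE 0.41) and Sirt1 at -0.24 (SE 0.18). Mock + NR also had lower mean log2 CPM than mock for alveolar type 2 (6.8 against 7.61) and fibroblast genes (6.27 against 6.86). The same held for mesothelial (4.24 against 5.32) and alveolar macrophage genes (3.75 against 4.45). Camera called 18 lists lower and 4 higher. A difference in dissection between these groups was not tested. Acta1 exceeded 1000 CPM in 2 of 5 mock + NR and 4 of 7 mock libraries. No gene passed in edgeR (0 genes, smallest adjusted p = 0.102), with 2875 at an unadjusted p under 0.05, 591 by DESeq2 and 994 by voom with quality weights. Leaving out mock replicate 6 gave 265 genes, and leaving out the muscle-rich libraries, chosen after the data were seen, 425. These 425 held 18 endothelial genes (list median -1.94, camera adjusted p = 2.7e-24, and adjusted p = 0.38 with an estimated correlation). They also held 6 alveolar type 1 genes (list median -1.60, camera adjusted p = 1.2e-12, and adjusted p = 0.41 with an estimated correlation).

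**Figure D3:**
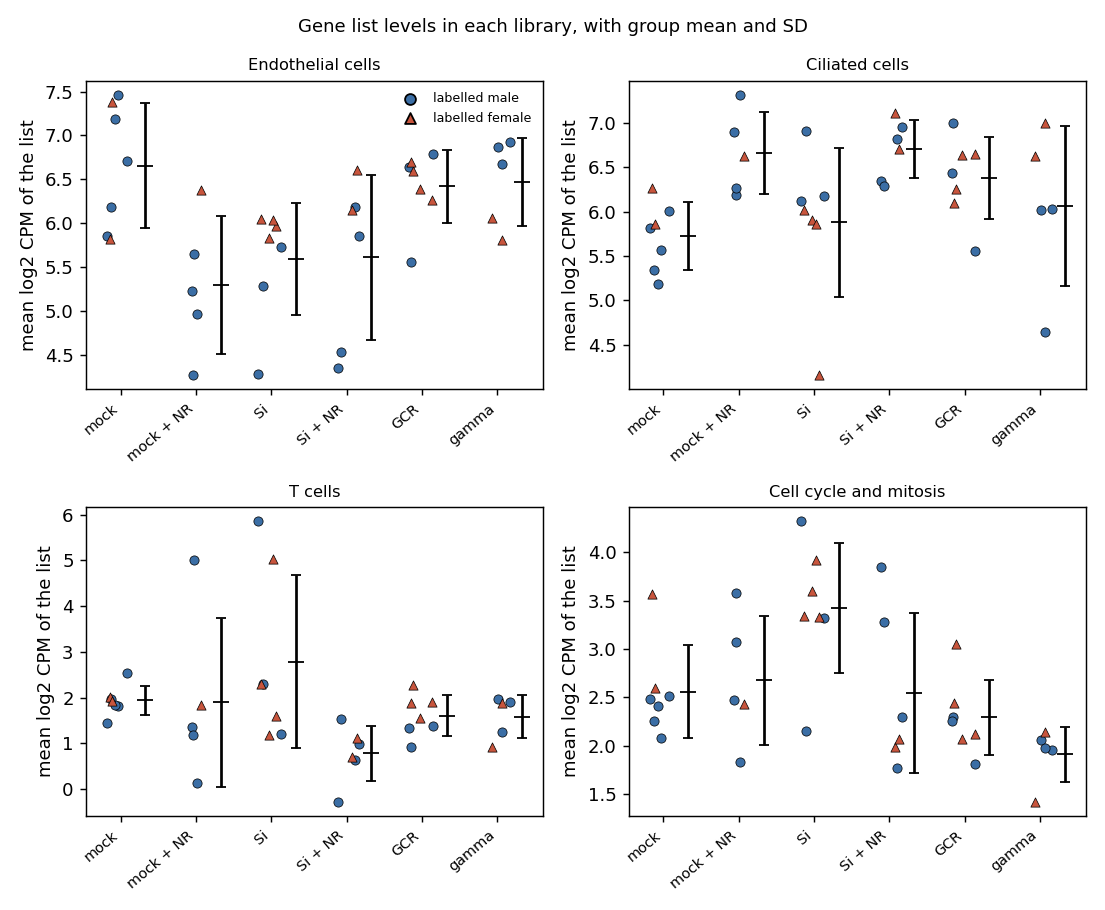
Mean log2 CPM of the endothelial, ciliated cell, T cell and cell cycle lists in each library by group, with circles for mice labelled male, triangles for mice labelled female, and group means with SD. The endothelial mean is 6.66 ± 0.71 in mock, 5.30 ± 0.78 in mock + NR and 5.60 ± 0.64 in silicon.

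In irradiated mice, silicon + NR lungs had less lymphocyte RNA than silicon lungs. B cell genes were lower in 18 of 19 members, and adjusted over the list alone 18 were lower and 1 higher (median -3.13, camera adjusted p = 4.63e-16, and adjusted p = 0.4 with an estimated correlation), with Pax5, which sets B cell identity, at -3.80 (SE 0.83) and Blk at -2.80 (SE 0.63). T cell genes were lower in 23 of 23, 22 when adjusted over the list alone (median -3.15, camera adjusted p = 4.63e-16, and adjusted p = 0.4 with an estimated correlation), as Cd3e of the T cell receptor at -3.69 (SE 0.87). Antigen presentation genes were lower in 31 of 31, with 15 when adjusted over the list alone (median -0.91, camera adjusted p = 3.9e-08, and adjusted p = 0.65 with an estimated correlation), as Ciita, the regulator of MHC class II, at -1.75 (SE 0.50). Cell cycle genes were lower in 32 of 32, none passing (median -0.76, camera adjusted p = 9.48e-13, and adjusted p = 0.4 with an estimated correlation), as Mcm5 at -1.08 (SE 0.38). Ciliated cell genes were higher in 26 of 26, none passing (median 0.69, camera adjusted p = 1.96e-15, and adjusted p = 0.4 with an estimated correlation). The clock gene Per3 stood at 1.30 (SE 0.33), Nmrk1 at -0.23 (SE 0.15) and Cd38, an NAD-consuming enzyme of leukocytes, at -1.14 (SE 0.40). The lymphoid-rich silicon replicates 3 and 6 had T cell means of 5.85 and 5.04 log2 CPM, against 1.19 to 2.30 in the other 5. The B cell median without the lymphoid-rich libraries was -1.54 (camera adjusted p = 5.55e-11, and adjusted p = 0.42 with an estimated correlation) and the T cell median -0.83 (camera adjusted p = 1.27e-08, and adjusted p = 0.42 with an estimated correlation). The cell cycle median was then -0.39 (camera adjusted p = 8.84e-06, and adjusted p = 0.77 with an estimated correlation), and antigen presentation genes were not called (median -0.13). Muscle-rich, with Acta1 over 1000 CPM, were 5 of 7 silicon and 2 of 6 silicon + NR libraries. With edgeR 0 genes passed (smallest adjusted p = 0.0663), with 2171 at an unadjusted p under 0.05 (893 without the lymphoid-rich libraries), 353 by DESeq2 and 4207 by voom with quality weights. Leaving out 1 library gave 0 to 336 genes, and 179 were called without the muscle-rich libraries, chosen after the data were seen, with silicon replicates 1 and 3 left. Ciliated cell genes were then not called (median 0.16, camera adjusted p = 0.172), and the cell cycle median was -1.65 (camera adjusted p = 1.29e-13, and adjusted p = 0.26 with an estimated correlation).

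Silicon in mice given NR was compared with mock + NR. The p53 targets were higher in 23 of 30 members, none passing singly or when adjusted over the list alone, by a small median of 0.13 (camera adjusted p = 0.00126, and adjusted p = 0.019 with an estimated correlation). Fry, which does not compare the list with other genes, gave adjusted p = 0.98. Psrc1 stood at 0.77 (SE 0.35), Zmat3 at 0.40 (SE 0.20), Zfp365 at 0.55 (SE 0.30) and Cdkn1a at 0.24 (SE 0.42). Heat shock genes were higher in 15 of 15 (median 0.64, camera adjusted p = 5.96e-12, and adjusted p = 0.22 with an estimated correlation), with Hsph1 at 1.19 (SE 0.39), and 0 passed when adjusted over the list alone. T cell genes were lower in 23 of 23, with 19 when adjusted over the list alone (median -2.31, camera adjusted p = 5.24e-16, and adjusted p = 0.29 with an estimated correlation). B cell genes were lower in 18 of 19, with 13 when adjusted over the list alone (median -1.84, camera adjusted p = 3.98e-11, and adjusted p = 0.34 with an estimated correlation). Cd3e stood at -2.80 (SE 0.88) and Cr2, the complement receptor of B cells, at -2.29 (SE 0.77). Ccl19 was at 419 CPM in mock + NR replicate 4, against a mean of 5.72 ± 3.71 in silicon + NR (SD, n = 6). The T cell median without the lymphoid-rich libraries was -0.42 (camera adjusted p = 2.05e-06, and adjusted p = 0.47 with an estimated correlation), the B cell median -0.52 (camera adjusted p = 0.00118, and adjusted p = 0.85 with an estimated correlation) and Cd3e -0.85 (SE 0.47). Acta1 exceeded 1000 CPM in 2 of 6 and 2 of 5 libraries. For single genes edgeR called 0 (367 at an unadjusted p under 0.05, voom with quality weights 0), and DESeq2 1. With an estimated correlation the p53 call had adjusted p = 0.017 without the lymphoid-rich and 0.025 without the heart-rich libraries. It was lost without the muscle-rich ones, chosen after the data were seen, with a median of 0.08 and camera adjusted p = 0.0126, and adjusted p = 0.32 with an estimated correlation. The B cell median was then -3.05 (camera adjusted p = 3.12e-09, and adjusted p = 0.34 with an estimated correlation).

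The difference between these silicon effects, the interaction with NR, was tested directly. Endothelial genes had positive interactions in 24 of 24 members, 19 when adjusted over the list alone (median 1.57, camera adjusted p = 2.71e-21, and adjusted p = 0.26 with an estimated correlation), with Tmem100 at 2.59 (SE 0.64) and Ramp2 at 2.62 (SE 0.70). T cell genes had negative ones in 23 of 23, 21 when adjusted over the list alone (median -4.16, camera adjusted p = 1.88e-12, and adjusted p = 0.36 with an estimated correlation), with Ccr7 at -6.20 (SE 1.39). B cell genes had negative ones in 18 of 19, 17 when adjusted over the list alone (median -3.91, camera adjusted p = 7.48e-13, and adjusted p = 0.26 with an estimated correlation). Clock genes were positive in 15 of 20, 6 when adjusted over the list alone (median 0.66, camera adjusted p = 0.000416, and adjusted p = 0.26 with an estimated correlation), as Ciart at 2.45 (SE 0.62). Lymphoid-rich libraries made up 2 of 7 silicon and 1 of 5 mock + NR libraries. Without them the T cell median was -0.13 and the list was not called (camera adjusted p = 0.856), with Ccr7 at 0.05 (SE 0.70). The B cell median was then -0.94 (camera adjusted p = 0.00241, and adjusted p = 0.85 with an estimated correlation). Clock genes were not called (median 0.38), and the endothelial median was 1.54 (camera adjusted p = 3.93e-21, and adjusted p = 0.43 with an estimated correlation). Muscle-rich libraries made up 4 of 7 mock, 5 of 7 silicon, 2 of 5 mock + NR and 2 of 6 silicon + NR libraries. At the level of genes edgeR called 0 (smallest adjusted p = 0.0821), with 1689 at an unadjusted p under 0.05, 327 by DESeq2, 0 by voom with quality weights, and 1335 without the muscle-rich libraries, chosen after the data were seen. In that fit, with silicon replicates 1 and 3 left, 21 endothelial genes were called (median 3.42, camera adjusted p = 6.06e-28, and adjusted p = 0.24 with an estimated correlation). It also called 17 B cell genes (median -5.94, camera adjusted p = 2.66e-09, and adjusted p = 0.37 with an estimated correlation) and 2 clock genes (median 1.13, camera adjusted p = 0.01, and adjusted p = 0.44 with an estimated correlation). Leaving out 1 library gave 0 to 151 genes, as listed further below.

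Radiation types were then compared with each other at the same dose. Silicon and gamma lungs differed in 42 genes, 10 higher and 32 lower in silicon. The higher ones included genes of mitosis, with Cdca8 at 2.30 (SE 0.51), Kif11 at 1.98 (SE 0.45) and Kif23 at 1.58 (SE 0.35), and Uhrf1, which maintains DNA methylation, at 1.55 (SE 0.35). Cell cycle genes were higher in 32 of 32 members, of which 2 rose, and 31 when adjusted over the list alone (median 1.75, camera adjusted p = 7.13e-26, and adjusted p = 0.38 with an estimated correlation). Genes lower in silicon included the matrix proteoglycan Podn at -2.39 (SE 0.43), the transcription factor Tbx5 at -2.11 (SE 0.43), Igf2 at -1.90 (SE 0.41) and the vessel growth factor Angpt1 at -1.39 (SE 0.31). Endothelial genes were lower in 24 of 24, 17 when adjusted over the list alone (median -1.01, camera adjusted p = 1.33e-11, and adjusted p = 0.61 with an estimated correlation), as Eng at -1.63 (SE 0.42). Of the 32 lower genes, 4 belonged to the sex label genes, in a comparison that holds the library labelled female gamma replicate 5. Acta1 exceeded 1000 CPM in 5 of 7 silicon and 0 of 5 gamma libraries, and 2 of 7 silicon libraries were lymphoid-rich and 2 of 5 gamma libraries heart-rich. Without the lymphoid-rich libraries edgeR called 0 genes (2406 at an unadjusted p under 0.05), with a cell cycle median of 1.47 (camera adjusted p = 1e-16, and adjusted p = 0.63 with an estimated correlation). Without the heart-rich ones it called 5, with a cell cycle median of 1.68 (camera adjusted p = 2.69e-12, and adjusted p = 0.56 with an estimated correlation). Without the muscle-rich libraries, chosen after the data were seen, 290 genes were called, of which 9 were among the 42. The endothelial median was then -1.83 (camera adjusted p = 1.86e-21, and adjusted p = 0.37 with an estimated correlation), with silicon replicates 1 and 3 left. The cell cycle median was 1.77 (camera adjusted p = 5.13e-15, and adjusted p = 0.37 with an estimated correlation). Cell cycle means were 2.15 log2 CPM in silicon replicate 1, 4.32 in replicate 3 and 1.42 to 2.14 in gamma. The balance turned in other fits, with 787 higher and 388 lower by DESeq2, 3344 and 1887 by voom with quality weights, 148 and 21 in a fit of only silicon and gamma, and 148 and 142 without the muscle-rich libraries. Leaving out 1 library gave 1 to 378 genes, as listed further below.

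GCR and gamma lungs differed in 967 genes, 451 higher and 516 lower in GCR. Cardiac muscle genes fell in 9 of 28 members, 26 when adjusted over the list alone (median -3.15, camera adjusted p = 5.04e-07, and adjusted p = 0.98 with an estimated correlation), with the natriuretic peptide gene Nppa at -6.02 (SE 1.82), the myosin gene Myh6 at -4.13 (SE 1.20) and Pln at -3.26 (SE 0.90). Fatty acid oxidation genes fell in 6 of 25, 16 when adjusted over the list alone (median -1.34, camera adjusted p = 0.00133, and adjusted p = 0.98 with an estimated correlation), as Etfdh at -2.18 (SE 0.58) and Acadl at -1.49 (SE 0.45). Nppa stood at 17519 and 24514 CPM in gamma replicates 3 and 4 and at 6.2 to 110 in the other 3. Without these 2 heart-rich libraries 4 genes were called, all among the 967, the cardiac median was -0.21 and the fatty acid oxidation median -0.04, neither list was called, and Nppa stood at 1.65 (SE 1.76). Ribosomal protein genes rose in 14 of 30, 24 when adjusted over the list alone (median 0.75, camera adjusted p = 1.88e-13, and adjusted p = 0.98 with an estimated correlation), as Rplp1 at 1.76 (SE 0.39) and Rps21 at 1.84 (SE 0.44), beside 3 high-Rn45s libraries in GCR and 0 in gamma. Without the high-Rn45s libraries the ribosomal protein median was 0.39 (camera adjusted p = 6.9e-08, and adjusted p = 0.85 with an estimated correlation). The count became 644 without the lymphoid-rich libraries, 0 without the high-Rn45s libraries, 0 without the muscle-rich ones (none of which is in these groups) and 0 in a fit of only GCR and gamma, all but the last chosen after the data were seen. Leaving out single libraries gave 0 to 2618, as listed further below.

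Silicon and GCR lungs differed in 5999 genes, 3605 higher and 2394 lower in silicon. Skeletal muscle genes were higher in silicon in 21 of 21 members, all passing (median 8.13, camera adjusted p = 4.25e-06, and adjusted p = 0.87 with an estimated correlation), with Myh2 at 11.14 (SE 2.48). Squamous genes rose in 16 of 18, 17 when adjusted over the list alone (median 6.09, camera adjusted p = 2.78e-05, and adjusted p = 0.87 with an estimated correlation), as Trp63, the basal cell factor, at 4.48 (SE 1.13). Cell cycle genes rose in 22 of 32, 26 when adjusted over the list alone (median 1.16, camera adjusted p = 5.1e-06, and adjusted p = 0.87 with an estimated correlation), as Cdc20 at 2.24 (SE 0.56) and Ccnb1 at 2.32 (SE 0.60). T cell genes rose in 18 of 23, 20 when adjusted over the list alone (median 2.24, camera adjusted p = 0.0349, and adjusted p = 0.9 with an estimated correlation), as Cd4 at 2.71 (SE 0.74). Without the lymphoid-rich libraries, 2 of which are silicon, the T cell median was 0.07 and the list was not called (camera adjusted p = 0.71), Cd4 stood at 0.65 (SE 0.49), and 6 cell cycle genes rose (median 0.84, camera adjusted p = 0.0013, and adjusted p = 0.92 with an estimated correlation). Oxidative phosphorylation genes rose in 25 of 34, 28 when adjusted over the list alone (median 1.16, camera adjusted p = 1.21e-05, and adjusted p = 0.88 with an estimated correlation), as Uqcrc1 at 2.11 (SE 0.50). Endothelial genes fell in 10 of 24, 15 when adjusted over the list alone (median -0.92, camera adjusted p = 2.78e-05, and adjusted p = 0.87 with an estimated correlation), as Ptprb at -1.52 (SE 0.40) and the VEGF receptor Kdr at -1.03 (SE 0.32). Alveolar type 1 genes fell in 6 of 17, 9 when adjusted over the list alone (median -0.96, camera adjusted p = 2.78e-05, and adjusted p = 0.87 with an estimated correlation), as the surface protein Pdpn at -1.15 (SE 0.29). Acta1 exceeded 1000 CPM in 5 of 7 silicon and 0 of 7 GCR libraries, and Rn45s 100000 CPM in 0 and 3. Without the muscle-rich libraries 1263 genes were called, 983 of them among the 5999, and 0 without the high-Rn45s libraries or with both levels as covariates, all chosen after the data were seen. Without the muscle-rich ones, with silicon replicates 1 and 3 left, the medians were 2.46 for skeletal muscle, 1.72 for squamous, 0.51 for oxidative phosphorylation, 3.39 for T cell, -1.73 for endothelial and -2.18 for alveolar type 1 genes. Each of these lists had a camera adjusted p of 0.0125 or less, and adjusted p = 0.55 or more with an estimated correlation.

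**Figure D4:**
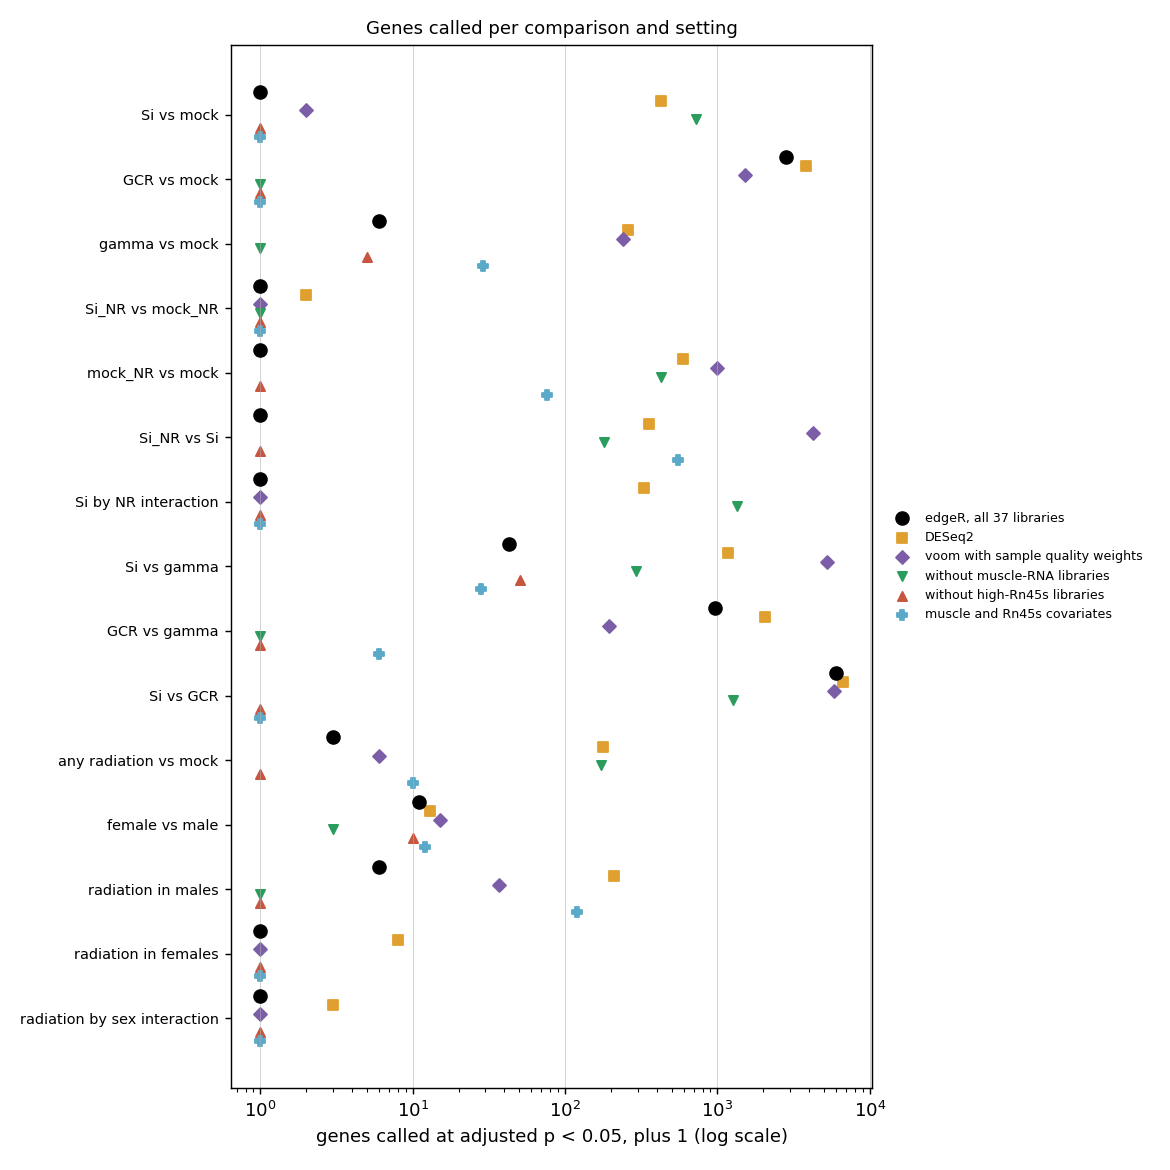
Genes called at an adjusted p under 0.05, plus 1, on a log axis, for each of the 15 comparisons. Black circles are edgeR on all 37 libraries, as 2811 for GCR against mock, and the other symbols are DESeq2, voom with quality weights, and 3 fits chosen after the data were seen, in which GCR against mock has 0.

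The radiation average was also tested within each sex. In males the clock gene Npas2 (chromosome 1, 39193731 to 39363236) rose by 2.08 (SE 0.36, adjusted p = 0.0207 by edgeR). Zbtb16 fell by 1.73 (SE 0.31), Cys1, a protein of primary cilia, by 1.62 (SE 0.26), the clock-driven factor Hlf by 1.39 (SE 0.25) and the stress factor Ddit3 by 1.00 (SE 0.18). Clock genes in males were lower in 15 of 20 members, with 1 rising and 1 falling, and 3 and 10 when adjusted over the list alone (median -0.67, camera adjusted p = 0.000498, and adjusted p = 0.42 with an estimated correlation), Dbp standing at -1.86 (SE 0.40) and Ciart at -1.67 (SE 0.35). The male calls, 5 in all, became 0 without the muscle-rich or the high-Rn45s libraries and 2 without the lymphoid-rich ones (chosen after the data were seen), and 207 by DESeq2. Leaving out 1 library gave 0 to 9 genes, as listed further below.

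In females edgeR called 0 genes (342 at an unadjusted p under 0.05, 7 by DESeq2, 0 by voom with quality weights), with 2 mock mice labelled female. Of the 2 gamma mice labelled female, replicate 5 went against its label. Egr1 stood at 2.03 (SE 0.64) and Cdkn1a at -1.01 (SE 0.43). Ribosomal protein genes were higher in 30 of 30 members, none passing (median 0.52, camera adjusted p = 1.68e-15, and adjusted p = 0.86 with an estimated correlation). Their median without the high-Rn45s libraries was 0.25 (camera adjusted p = 2.11e-08, and adjusted p = 0.88 with an estimated correlation). The interaction of radiation with sex called 0 genes in edgeR (183 at an unadjusted p under 0.05, 2 by DESeq2, 0 by voom with quality weights). Clock genes had interactions that were positive in 16 of 20 members, and adjusted over the list alone 7 were positive and 2 negative (median 0.77, camera adjusted p = 1.95e-07, and adjusted p = 0.11 with an estimated correlation), with Hlf at 2.07 (SE 0.48), Per3 at 1.52 (SE 0.54), Npas2 at -2.07 (SE 0.53) and Arntl at -1.97 (SE 0.60). Clock means were 4.94 and 4.52 log2 CPM in the mock libraries labelled female and 5.05 to 5.42 in those labelled male. Acta1 exceeded 1000 CPM in 1 of the 2 mock libraries labelled female and 3 of the 5 labelled male. Of irradiated ones without NR, silicon replicate 2 (labelled male) and replicates 4 to 7 (labelled female) exceeded it.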

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

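The tests of Rn45s and of muscle RNA on the GCR genes, both tests of the muscle-rich libraries, all fits without muscle-rich, high-Rn45s, lymphoid-rich or heart-rich libraries, and the tallies of splits by kind of library were chosen only after the results were seen. The depth test, the NR test of Egr1 and the splits of samples were set before. The wording of 1 Egr1 explanation was narrowed after its result, from irradiation itself to irradiation with or without NR, and the bound set for it was found wrong after its result, as given there.

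GCR against mock called 2811 genes, with a median log2 fold change in the called direction of 0.82 (quartiles 0.59 and 1.25), and a difference in depth is argued against, since 2443 genes were called after thinning every library to 9485197 counts, 2241 of them called before in the same direction. Without the 4 muscle-rich mock libraries the median was 0.65 (quartiles 0.44 and 0.93), 78.9% of that with all. This was the lowest of 35 choices of 4 mock libraries. It cannot exclude muscle RNA as the cause, as the genes were picked with these libraries. With all 13 muscle-rich libraries left out edgeR called 0 genes (3235 at an unadjusted p under 0.05), in a fit with 3 mock libraries and smaller folds, and for the 31 called skeletal muscle and squamous epithelium genes muscle RNA stays open as the cause, since -6.94% of their median was left (from 4.30 to -0.30). High Rn45s cannot be told apart from GCR as the cause, since without those 4 libraries the median was 0.54 (quartiles 0.36 and 0.91), 66.1% of that with all and rank 4 from the lowest of 100 choices of 3 GCR and 1 mock libraries. The signed mean over the called genes was 1.39 to 1.54 in the 3 high-Rn45s GCR libraries, but already 1.35 in GCR replicate 1 with 4.81% Rn45s (0.4 to 0.9 in the other 3), and 0.01 in the high-Rn45s mock library against -0.45 to 0.48 in the other mock libraries, a single library that excludes nothing, and radiation itself or a separate GCR cohort also stays open.

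Skeletal muscle RNA was high in 13 libraries, and a response to irradiation is argued against, since 6 of the 12 unirradiated libraries held it. A candidate source is tissue other than lung parenchyma and airways in the dissected piece, since 12 of the 13 had a higher squamous epithelium score than each of the other 24 libraries. Of 21 muscle genes 15 were higher in all 13 libraries than in any other, and of 18 squamous genes 0 were. None of the 12 GCR and gamma libraries was among the 13, so that a difference in dissection between groups stays open, untested.

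Egr1 was higher with any radiation by 1.99 (SE 0.34), and by 1.91 (SE 0.57, adjusted p = 0.12 by edgeR) without either kind of library, which argues against those libraries as its cause. That call ended with a similar fold and a larger error, in a fit of 21 libraries. Silicon + NR against mock + NR gave 0.01 (SE 0.42), and the bound set before rested on the value for any radiation, which was wrong for this test, since silicon without NR gave only 1.18 (SE 0.37, adjusted p = 0.13) and 0.01 plus 2 SE reaches 0.84. Irradiation with or without NR thus cannot be told apart from an effect that NR removes, as the interaction of silicon with NR was -1.17 (SE 0.55, unadjusted p = 0.041, adjusted p = 0.46 by edgeR). Egr1 averaged 50.8 CPM in silicon and 42.9 in silicon + NR, but 23.1 in mock and 41.8 in mock + NR. Without the heart-rich libraries the value for any radiation was 1.73, and handling that differed between groups was not tested.

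Other splits of the samples, 40 with the real one, were refitted for 13 comparisons. Chance could be excluded for females against males (10 genes, highest other 1) and for silicon against GCR (5999, highest other 1316). The real silicon and GCR groups also part all 5 muscle-rich libraries from all 3 with high Rn45s, and without the latter edgeR called 0 genes (5284 at an unadjusted p under 0.05). Chance could not be excluded for GCR against mock (2811, highest other 3753), GCR against gamma (967, 3595), silicon against gamma (42, 1713), gamma against mock (5, 133), any radiation (2, 2635) or radiation in males (5, 1196). Where edgeR called 0 genes in the real groups, the highest other split gave 0 for silicon and for mock + NR against mock, 870 for silicon + NR against mock + NR, 234 for silicon + NR against silicon and 2350 for the NR interaction. Splits that called several times the real count, as in GCR against gamma, silicon against gamma, gamma against mock, any radiation and males, point to a structure of the samples. In GCR against gamma 9 other splits had all 3 high-Rn45s libraries on 1 side, as the real groups do, and 5 of these called over 100 genes (0 to 3595 in all 9), against 1 of the 30 that divided them (1043). In GCR against mock 4 other splits had all 4 on 1 side, and 2 of these called over 100 (0 to 3753), against 2 of 35 (at most 1132). Without these libraries edgeR called 0 genes in both (1608 and 2748 at an unadjusted p under 0.05). In silicon against gamma the 2 other splits with all 5 muscle-rich libraries on 1 side called 174 and 1713, and 1 of the 37 others called over 100 (302). In any radiation the 1 split with all 9 on 1 side called 2635, and 1 of the 38 others called over 100 (282).

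In 19 of 168 groups of values 1 library lay far from the others, where chance gives about 1 in 20, or 8.4. The values given are the gap to the nearest library over the range of the group. The total of GCR replicate 4 was high (0.639). Among p53 targets, Cdkn1a (0.723) and Phlda3 (0.821) were high in mock + NR replicate 2 and Phlda3 in gamma replicate 3 (0.811), while Mdm2 was low in mock replicate 4 (0.572) and Bax in silicon + NR replicate 4 (0.632) and GCR replicate 6 (0.779). Adipose genes were low in mock + NR replicate 3 (0.785) and high in gamma replicate 3 (0.712), and liver genes high in silicon replicate 1 (0.643). Low were B cell genes in gamma replicate 4 (0.716), endothelial genes in GCR replicate 2 (0.578), ciliated (0.619) and club cell genes (0.642) in silicon replicate 4, and alveolar type 1 genes in silicon replicate 3 (0.701). Cell cycle genes were high in mock replicate 6 (0.65) and low in gamma replicate 4 (0.732), and interferon genes low in mock replicate 3 (0.601) and high in GCR replicate 4 (0.675). By tests of the difference itself, radiation types differed in 5999 genes (silicon and GCR), 967 (GCR and gamma) and 42 (silicon and gamma). The effect of silicon differed with NR in 25 gene lists, and that of radiation between the sexes in 21, with camera's preset correlation and 0 of either with an estimated one.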

How the results depend on the processing

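The fits without muscle-rich, high-Rn45s, lymphoid-rich or heart-rich libraries and those with covariates were chosen only after the data were seen, and the other alternatives before. Numbers of called genes that moved by over 1.5 times are given by setting, and the cause was not tested unless stated. DESeq2 called 425 in silicon against mock, 259 in gamma against mock, 1 in silicon + NR against mock + NR and 591 in mock + NR against mock. It also called 353 in silicon + NR against silicon, 327 in the NR interaction, 1175 in silicon against gamma and 2061 in GCR against gamma. It further called 176 in any radiation, 207 in males, 7 in females and 2 in the sex interaction. Voom with quality weights called 1 in silicon against mock, 1516 in GCR against mock, 238 in gamma against mock and 994 in mock + NR against mock. It also called 4207 in silicon + NR against silicon, 5231 in silicon against gamma, 192 in GCR against gamma and 5 in any radiation. It further called 36 in males. The fit of only the groups compared called 909 in GCR against mock, 0 in gamma against mock, 169 in silicon against gamma and 0 in GCR against gamma. It also called 134 in any radiation. Without a count filter the number was 573 in GCR against gamma, with RLE size factors 1 in any radiation and without the sex term 6 in any radiation.

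The fit without the muscle-rich libraries called 725 in silicon against mock, 0 in GCR against mock, 0 in gamma against mock and 425 in mock + NR against mock. It also called 179 in silicon + NR against silicon, 1335 in the NR interaction, 290 in silicon against gamma and 0 in GCR against gamma. It further called 1263 in silicon against GCR, 170 in any radiation, 2 in females against males and 0 in males. The fit without either kind of library called 1120 in silicon against mock, 0 in GCR against mock, 1 in gamma against mock and 870 in mock + NR against mock. It also called 1691 in the NR interaction, 781 in silicon against gamma, 0 in GCR against gamma and 926 in silicon against GCR. It further called 220 in any radiation, 3 in females against males and 0 in males. The fit without the high-Rn45s libraries called 0 in GCR against mock, GCR against gamma, silicon against GCR, any radiation and males. The fit with muscle and Rn45s as covariates called 0 in GCR against mock, 28 in gamma against mock, 75 in mock + NR against mock and 548 in silicon + NR against silicon. It also called 27 in silicon against gamma, 5 in GCR against gamma, 0 in silicon against GCR and 9 in any radiation. It further called 119 in males. The fit without the lymphoid-rich libraries called 2 in gamma against mock, 0 in silicon against gamma, 644 in GCR against gamma and 0 in any radiation. It also called 2 in males. The fit without the heart-rich libraries called 5 in silicon against gamma and 4 in GCR against gamma. These edgeR fits hold fewer libraries or more terms, and radiation in females and its interaction with sex could not be fitted without the muscle-rich libraries, since no silicon library labelled female was left. At an unadjusted p under 0.05 the counts of 0 genes without the muscle-rich libraries became 3235 in GCR against mock, 1533 in gamma against mock, 4536 in GCR against gamma and 979 in males. Without either kind they had 1104 in GCR against mock, 1651 in GCR against gamma and 1130 in males. Without the high-Rn45s libraries they had 2748 in GCR against mock, 1608 in GCR against gamma, 5284 in silicon against GCR, 1429 in any radiation and 1707 in males. Without the lymphoid-rich ones they had 2406 in silicon against gamma and 2067 in any radiation. With covariates they had 1571 in GCR against mock and 1931 in silicon against GCR, and with only the groups compared 1530 in gamma against mock and 2645 in GCR against gamma.

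Leaving out 1 library at a time, the number of called genes ran from 0 to 307 in silicon against mock. It was 501 to 4087 (without GCR replicate 4) in GCR against mock. It was 1 to 18 in gamma against mock and 0 to 265 in mock + NR against mock. It was 0 to 336 in silicon + NR against silicon and 0 to 151 in the NR interaction. It was 1 to 378 in silicon against gamma and 0 to 2618 in GCR against gamma. It was 4694 (without silicon replicate 4) to 6811 (without GCR replicate 4) in silicon against GCR and 0 to 30 in any radiation. It was 10 to 11 (without gamma replicate 5) in females against males and 0 to 9 in males. It stayed 0 by edgeR in silicon + NR against mock + NR, females and the sex interaction. The libraries whose absence moved a number by over 1.5 times, each left out alone, were these. Silicon against mock moved from 0 to 163 without mock replicate 3 and 307 without mock replicate 6. GCR against mock moved from 2811 to 1821, 501, 1132 and 1536 without GCR replicates 1, 2, 5 and 6. It moved to 1516, 1560 and 1400 without mock replicates 3, 5 and 6. Gamma against mock moved from 5 to 1 without mock replicates 1, 3, 6 and 7, 2 without mock replicates 2, 4 and 5 and 12 without gamma replicates 1 and 5. It moved to 18 without gamma replicate 2. Mock + NR against mock moved from 0 to 265 without mock replicate 6. Silicon + NR against silicon moved from 0 to 336, 249, 127 and 220 without silicon replicates 1, 2, 4 and 5. The NR interaction moved from 0 to 151, 20 and 125 without silicon replicates 2, 4 and 5. It moved to 29 and 147 without mock + NR replicates 2 and 3. Silicon against gamma moved from 42 to 378, 27, 4, 2, 1, 1 and 22 without silicon replicates 1 to 7. It moved to 5, 7 and 178 without gamma replicates 3, 4 and 5. GCR against gamma moved from 967 to 0, 0, 2618, 0, 1 and 2008 without GCR replicates 1, 2, 4, 5, 6 and 7. It moved to 638, 5, 4 and 2149 without gamma replicates 1, 3, 4 and 5. Any radiation moved from 2 to 0 without silicon replicates 1 and 2, GCR replicates 1 and 3, gamma replicate 3 and mock replicates 1, 2, 3, 4 and 7, 1 without silicon replicates 3, 5, 6 and 7, GCR replicates 5, 6 and 7 and gamma replicates 1, 2 and 5 and 5 without GCR replicate 4. It moved to 30 without mock replicate 6. Males moved from 5 to 0 without silicon replicate 1, gamma replicate 2 and mock replicates 1 and 4, 2 without silicon replicate 3 and mock replicate 3 and 3 without GCR replicate 2 and mock replicate 5. It moved to 8 without silicon replicate 2 and 9 without GCR replicate 3.

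Of the gene lists, an estimated correlation left 1 in silicon + NR against mock + NR and females against males and 0 in the other 13 comparisons. Fry called 15 in silicon against GCR (camera 21) and 3 in GCR against mock. It called 1 in silicon against gamma, GCR against gamma, any radiation and females against males, and 0 in the other comparisons. Voom with quality weights called 23 in gamma against mock. With the muscle-rich libraries left out camera called 29 in gamma against mock, 28 in any radiation and 30 in males, and with the heart-rich ones left out 26 in gamma against mock and 7 in GCR against gamma. The correlation of fold changes turned from -0.26 to 0.28 between silicon and GCR, both without the muscle-rich libraries and without either kind, and from -0.14 to 0.47 and 0.46 between silicon and gamma. Between GCR and gamma it moved from 0.62 to 0.42 without the muscle-rich libraries and to 0.43 with the mock mice split. The cause was not tested.

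Among the 335 gene values named, a sign turned in 47 cases in which the value passed in the main or the other fit. The cause was not tested. Turns of values that passed in neither fit were not counted, as those of Ccr7 without the lymphoid-rich libraries. In GCR against mock the log2 fold change without the muscle-rich libraries was 1.86 for Myh4, 1.97 for Myh8, 2 for Mybpc1, 1.09 for Sim2 and 1.64 for Acta1. It was 0.79 for Tnnt3, 0.72 for Mylpf, 1.75 for Krt4 and 0.82 for Krt13. Without either kind it was 0.17 for Myf6, 1.41 for Myh4, 1.31 for Myh8, 1.26 for Mybpc1 and 0.86 for Sim2. It was 1.1 for Acta1, 0.16 for Tpm2, 0.77 for Tnnt3, 0.36 for Mylpf and 1.86 for Krt4. It was 0.95 for Krt13. With covariates it was -0.01 for Lars2, 0.25 for Myh4, 0.39 for Myh8, 0.53 for Acta1 and 0.28 for Uqcrc1. It was 0.09 for Sdhb. In silicon against GCR with covariates it was -0.02 for Myh2, -0.72 for Myh1, -0.35 for Pvalb, -0.51 for Myh4 and -0.41 for Myh8. It was 0.20 for Snora81, 0.13 for Lars2 and 0.05 for Sftpd. Without either kind it was 0.61 for Snora81. In GCR against gamma voom gave 0.95 for Alpk2, 0.19 for Adprhl1 and 0.22 for Nkx2-5. Without the heart-rich libraries it was 2.41 for Nppb, 1.65 for Nppa, 0.25 for Cilp2, 0.64 for Alpk2 and 0.36 for Corin. It was 0.23 for Adprhl1 and 0.22 for Nkx2-5. In gamma against mock Eif2s3y was -0.07 with voom and -0.10 without gamma replicate 5, and ran up to 7.15 (without gamma replicate 1 or 2) when 1 other library was left out, and was 7.52 without both heart-rich libraries. In the counts that follow, a value that passed in neither fit counts as kept, whichever its sign. Of the 335 values, 239 kept direction and side of the threshold in this sense with DESeq2, 331 with RLE size factors, 318 without a count filter and 241 with voom. The number was 227 without the high-Rn45s, 296 without the lymphoid-rich and 291 without the heart-rich libraries, and 200 with covariates. Of those that could be computed, 147 of 308 did without the muscle-rich libraries, 146 of 306 without either kind, 270 of 283 without the sex term and 222 of 275 with only the groups compared. Leaving out 1 library, 5055 of 5630 did. Of depth, only GCR against mock was tested, with 2443 genes called after thinning against 2811. No paired analysis was possible because each mouse gave 1 library and replicate numbers only name mice.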

Other observations

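The values in this part were chosen after the data were seen, and no further test was run on them here. In 3 libraries, silicon replicates 3 and 6 and mock + NR replicate 4, genes of organized lymphoid tissue stood far above the rest. Glycam1, a mucin of high endothelial venules, through which lymphocytes enter lymph nodes, was at 48.9, 492 and 77.6 CPM and at most 4.14 elsewhere. These 3 libraries belong to 1 irradiated and 1 unirradiated group, and the B and T cell lists of the silicon comparisons include them.

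Fat and surfactant genes also differed between mice. The mean of the adipose list was 8.74 log2 CPM in gamma replicate 3 and 2.07 to 3.99 in the other gamma libraries. Sftpc, the surfactant protein of alveolar type 2 cells, ran from 307 CPM in mock + NR replicate 2 to 36040 in mock replicate 1.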
